A study of Homo sapiens with 18 samples.

How the data were processed

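RNA was sequenced from 18 samples of cardiomyocytes derived from induced pluripotent stem cells (iPSC), in 6 groups of 3. Total RNA was extracted with a column kit and stranded libraries were made, per the labels' protocols. The deposited count table holds whole-number read counts per gene, not normalized, with 1 column per sample. Per the submitters' processing notes, which give names without order or role, the tools were Trim Galore, STAR 2.7.10, Cufflinks 2.1.1, HTSeq 0.6.1 and DESeq2, with the hg38 genome build. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may be mixed. The authors also deposited 4 comparison tables, for ASO1, ASO3, ASO4 and ASO control against non-treated cells. Per the file headers these tables hold log2 fold changes, p-values and adjusted p-values in the format of DESeq2, and an adjusted p given as missing was left missing.

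The count table had 33121 rows that name a gene and 5 summary rows, which stayed out of library sizes and tests. The summary rows held reads in no annotated feature (16.1 to 19.0% of all reads per library), reads assigned ambiguously and reads aligning to several places. Reads assigned to genes ranged from 13942676 (CALM1 knock-in 1) to 28484884 (non-treated 3) per library. At this depth the biological coefficient of variation was 5.40%. Intervals and floors from counts cover counting error only, since reads without molecular identifiers are not independent molecules. Every pair of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom from 2.63 to 9.23. No pair is therefore a split of the reads of 1 library, but this does not tell technical from biological replicates. All 18 libraries were kept as separate samples, following the labels.

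Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 16968. Libraries were scaled with the trimmed mean of M-values (TMM), and 1 quasi-likelihood model was fitted to all 18 samples with a coefficient per group and no other covariate, leaving 12 residual degrees of freedom. The 8 contrasts set 5 groups against non-treated cells and ASO1, ASO3 and ASO4 against ASO control, and a joint F test compared ASO1, ASO3 and ASO4 with one another. P-values were adjusted with the Benjamini-Hochberg method over all genes tested within a contrast, and a gene was called at an adjusted p below 0.05. Levels are given as TMM-scaled CPM, the reads of a gene as a rate of all assigned reads, and log2 fold changes with the standard error (SE) from the model. The 95% intervals of log2 fold changes are normal approximations from that SE.

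The groups, contrasts, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Against non-treated cells, the rule named CALM1, CALM2 and CALM3, then the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 2 CPM in the higher group and no overlap between replicates. Against ASO control it named 5 in each direction, for the joint test the 10 genes of lowest p, and for each gene list with a called member up to 4 members of lowest p. Genes outside the rule are marked as chosen after their values were seen. Of 30 gene lists fixed for pathways, RNA quality and cell types, 28 had at least 5 tested members. The list of the 3 calmodulin genes was too short, and mitochondrially encoded protein genes were not analysed here because no row carried their symbols. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 28 lists within a contrast. The tests were repeated with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way. Positions came by gene symbol from GENCODE release 29 on GRCh38, and from RefSeq for symbols absent there, and were found for 15910 of the 16968 tested genes (93.8%). Genes with a mean of at least 1 CPM were used for medians along chromosomes. Chromosome 20 was split into arms at its widest gap between gene starts. Other autosomes split in this way gave 38 pieces of at least 20 genes, which need not be arms because the widest gap can miss the centromere. Medians of every run of neighbouring genes on the other autosomes, taken without a split and chosen after the data were seen, were therefore added.

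Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter on low counts, the replicate number as a block, a fit to the compared groups alone, and leaving out each library in turn. A fit without the knock-in libraries and a count without chromosome 20 genes were added after the data were seen. The model was tested on a simulated data set for each of 2 comparisons, with 200 genes changed by known folds. These genes had a mean of at least 5 CPM outside the knock-in group, so recovery at lower levels was not tested. For ASO3 against non-treated cells edgeR recovered 58.2% of those changed 1.2-fold, 97.0% of those changed 1.5-fold and 100% of those changed 2-fold. It tested 16725 genes there, with 3.66% false calls. For the knock-in comparison it recovered 49.3%, 91.0% and 100%, with 16714 genes tested and 5.98% false calls. That data set held far fewer changed genes than the real comparison called. DESeq2 recovered 61.2%, 97.0% and 100% with 10.1% false calls for ASO3, and 55.2%, 92.5% and 100% with 12.3% false calls for the knock-in. Planted shifts of -1 and 0.58 (log2) on the chromosome 20 arms came back as -0.99 and 0.59. None of 10 lists without change was called by camera with either correlation or by fry. These lists held random genes simulated independently. The preset correlation was therefore not tested for lists whose genes vary together. Overlaps between comparisons that share the non-treated libraries were set against 20 simulated data sets without change.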

Results

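Messenger RNA levels were measured in cardiomyocytes made from WTC, an established human iPSC line, to ask how antisense oligonucleotides (ASOs) that lower CALM1 change the transcriptome. CALM1, CALM2 and CALM3 are separate genes for the same calcium sensor, calmodulin, and calmodulinopathy is a heritable arrhythmia disorder caused by mutations in them. Wild-type cells received ASO1, ASO3, ASO4, a control oligonucleotide (ASO control) or vehicle (non-treated) for 24 h, and RNA was taken 7 days later. A further group carried a heterozygous CALM1 missense knock-in and received vehicle. For the knock-in group no exposure time and no time of RNA collection were recorded. Each of the 6 groups had 3 libraries, with 13942676 to 28484884 reads assigned to genes per library. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Mitochondrial ribosomal RNA took 1.90% ± 0.251 (SD, n = 3) of assigned reads in the knock-in group and 1.40% ± 0.0621 (SD, n = 3) in the non-treated group. In the library CALM1 knock-in 3, 12.5% of all reads aligned to several places (95% Wilson interval 12.53 to 12.55%), against at most 5.58% in the other 17 libraries.

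CALM1, on chromosome 14 (GRCh38, 90396502 to 90408261, plus strand), was lower with all 3 targeting oligonucleotides, and CALM2 and CALM3 were not called with any of them. In non-treated cells CALM1 stood at 183 ± 3.38 CPM (SD, n = 3), with ASO1 at 142 ± 5.10, with ASO3 at 154 ± 4.77 and with ASO4 at 123 ± 6.64. CALM1 thus changed by -22.8%, -16.3% and -33.0%, with log2 fold changes of -0.37 ± 0.05, -0.26 ± 0.05 and -0.58 ± 0.05 (SE). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p-values of 3.85e-05, 4.71e-04 and 9.96e-10. With ASO control CALM1 was at 194 ± 9.61 CPM (SD, n = 3), not distinguishable from non-treated cells (log2 0.08 ± 0.05, edgeR adjusted p = 0.597). Against ASO control the log2 fold changes were -0.45, -0.33 and -0.66 for ASO1, ASO3 and ASO4, with edgeR adjusted p-values of 5.43e-07, 1.50e-04 and 3.63e-11. CALM2 lay at 303 ± 8.89 CPM in non-treated cells and at 311 ± 7.33, 302 ± 9.20 and 292 ± 12.1 CPM with ASO1, ASO3 and ASO4 (SD, n = 3). CALM3 lay at 308 ± 3.15 CPM and at 322 ± 5.25, 311 ± 5.42 and 318 ± 1.35 CPM (SD, n = 3). The 95% intervals of their log2 changes against non-treated cells reached from -0.14 to 0.12 for CALM2 and from -0.06 to 0.15 for CALM3 over the 3 oligonucleotides. The summed level of the 3 genes was 794 ± 9.001 CPM in non-treated cells and 733 ± 17.4 CPM with ASO4 (SD, n = 3), and CALM1 made up 23.1% ± 0.194 and 16.7% ± 0.523 of it.

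**Figure D1:**
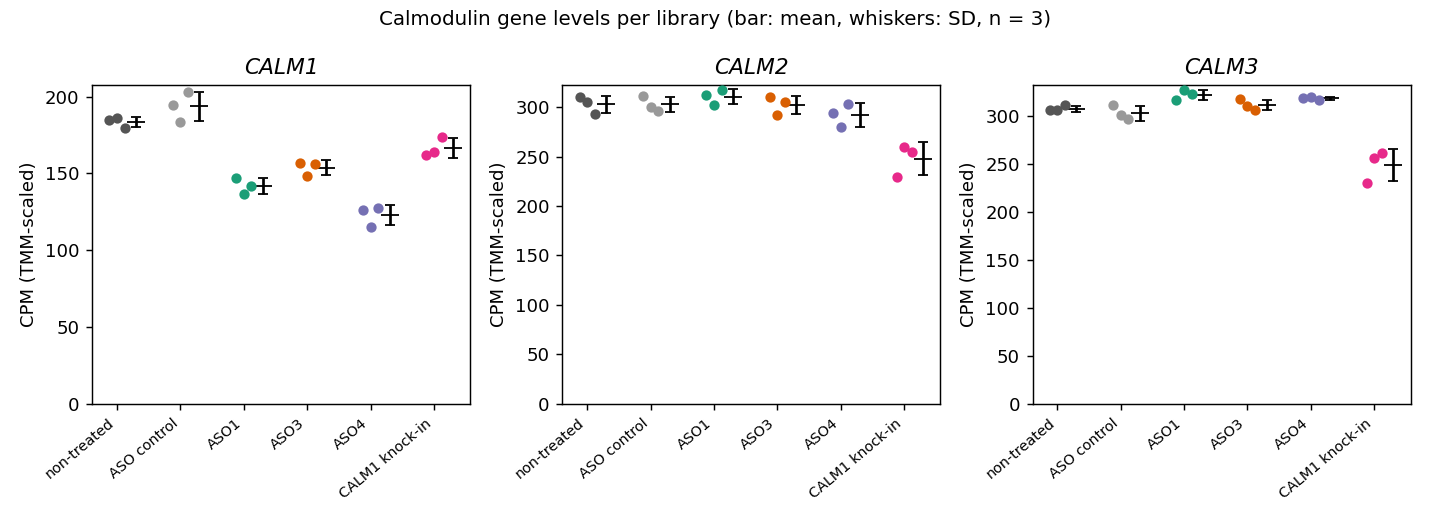
CPM of CALM1, CALM2 and CALM3 (vertical axes) in each of the 18 libraries by group, with the mean as a bar and the SD as whiskers (n = 3). CALM1 lies between 115 and 157 CPM in the 9 libraries with ASO1, ASO3 or ASO4 and between 180 and 203 CPM in the 6 non-treated and ASO control libraries.

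The oligonucleotides differed in how far they lowered CALM1. ASO4 lowered it further than ASO3, with a difference of -0.32 on the log2 scale (95% interval -0.41 to -0.23, edgeR adjusted p = 5.93e-04). The difference of ASO4 from ASO1 was -0.21 (95% interval -0.30 to -0.11), with an edgeR adjusted p of 0.106 over all genes and 3.09e-04 over the 3 calmodulin genes alone. The difference of ASO3 from ASO1 was 0.12 (95% interval 0.03 to 0.21), with an edgeR adjusted p of 0.161 over all genes and 0.0479 over the 3 genes alone.

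With ASO1, CALM1 fell and little else passed the test. The edgeR test called 2 genes, both lower, and 956 genes had an unadjusted p below 0.05 where chance gives 848.4. The other called gene was TRNT, the mitochondrial threonine transfer RNA, which fell by 0.54 on the log2 scale (SE 0.10, edgeR adjusted p = 0.0235) and was chosen after its values were seen. Of the 25 cholesterol synthesis genes, 0 were called by edgeR over all genes and 13 were higher adjusted over the list alone (camera adjusted p = 2.33e-12, adjusted p = 0.110 with an estimated correlation). Examples chosen after their values were seen are HMGCS1, an early enzyme of the pathway, at 224 ± 6.13 against 190 ± 12.03 CPM, and INSIG1, a sterol-regulated brake on it, at 37.0 ± 2.38 against 30.1 ± 1.87 CPM (SD, n = 3). Of the 32 glycolysis and hypoxia genes, 0 were called over all genes and 15 were lower adjusted over the list alone (camera adjusted p = 1.36e-08, adjusted p = 0.243 with an estimated correlation). Among them BNIP3, a hypoxia-induced mitophagy receptor chosen after its values were seen, was at 83.3 ± 13.98 against 117 ± 20.4 CPM (SD, n = 3). With ASO control BNIP3 was at 78.9 ± 4.88 CPM (SD, n = 3). Both lists moved the same way with ASO control against the same non-treated libraries, as given below, so neither change was particular to ASO1. Of the 28 lists, camera called 10 at the preset correlation and 0 with an estimated one, and fry called 1, cholesterol synthesis (fry adjusted p = 0.0411). The count of called genes was 10 without non-treated 3, 1 without non-treated 1, non-treated 4 or ASO1 3, 14 with DESeq2 and 31 when only the 6 libraries were fitted.

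With ASO4, CALM1 was the only gene the edgeR test called, and 1418 genes had an unadjusted p below 0.05. Of the 31 interferon-stimulated genes, 0 were called over all genes and 9 were higher adjusted over the list alone (camera adjusted p = 4.48e-07, adjusted p = 0.334 with an estimated correlation). Examples chosen after their values were seen are MX1, an antiviral GTPase, at 5.70 ± 1.52 against 1.503 ± 0.405 CPM, and ISG15, a ubiquitin-like modifier, at 17.8 ± 0.751 against 12.3 ± 0.216 CPM (SD, n = 3). Of the 30 sarcomere genes, 0 were called and 8 were higher adjusted over the list alone (camera adjusted p = 4.48e-07, adjusted p = 0.317 with an estimated correlation), among them ACTN2, which crosslinks actin at the Z-disc, at 1501 ± 102 against 1322 ± 47.8 CPM (SD, n = 3, chosen after its values were seen). Of the 39 ribosomal protein genes, 0 were called and 19 were lower adjusted over the list alone (camera adjusted p = 1.96e-21, adjusted p = 0.310 with an estimated correlation). Of the 28 lists, camera called 11 at the preset correlation and 0 with an estimated one, and fry called 0. The count of called genes was 131 without ASO4 4, 3 without ASO4 1, and 97 with DESeq2.

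With ASO3, 1184 genes changed, 573 higher and 611 lower, and 3324 had an unadjusted p below 0.05. The changes were small: the median size among called genes was 0.25 on the log2 scale, and 22 genes changed at least 2-fold. Some contractile and calcium-cycling genes were among those higher, and some cell cycle genes and epicardial markers among those lower. Of the 30 sarcomere genes 14 rose and 2 fell (18 and 3 adjusted over the list alone; camera adjusted p = 9.39e-07, adjusted p = 0.314 with an estimated correlation). ANKRD1, a stretch-responsive sarcomere protein, rose from 1984 ± 129 to 2622 ± 157 CPM (SD, n = 3; log2 0.40 ± 0.06 SE, edgeR adjusted p = 1.33e-04), and ACTN2, NEXN and SMPX rose by 0.28, 0.25 and 0.26 on the log2 scale. Of the 27 calcium handling genes 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.00657, adjusted p = 0.314 with an estimated correlation). RYR2, the calcium release channel of the sarcoplasmic reticulum, rose by 0.26 ± 0.05 (log2, SE), CASQ2, its calcium buffer, by 0.27 ± 0.05, and ATP2A2, the calcium pump SERCA2, by 0.26 ± 0.05. Of the 24 cardiac transcription factors 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 2.06e-04, adjusted p = 0.314 with an estimated correlation). MYOCD, a coactivator of muscle genes, rose by 0.29 and MEF2A by 0.23, and TBX18, also an epicardial factor, fell by 0.61 on the log2 scale.

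Of the 35 cell cycle genes 9 fell with ASO3 and 0 rose (20 and 0 adjusted over the list alone; camera adjusted p = 7.45e-09, adjusted p = 0.314 with an estimated correlation), among them MCM2 of the replicative helicase, TOP2A, a DNA topoisomerase, and MYBL2, with log2 fold changes of -0.26, -0.30 and -0.34. Of 18 smooth muscle and epicardial markers 8 fell and 4 rose (10 and 5 adjusted over the list alone), which was not called as a list (camera adjusted p = 0.0628, adjusted p = 0.314 with an estimated correlation). ALDH1A2, a retinoic acid synthesis enzyme of the epicardium, fell by 0.94 ± 0.14 (log2, SE), UPK3B by 0.80 ± 0.13 and KRT19 by 0.44 ± 0.07, and LMOD1, a smooth muscle actin nucleator, rose by 0.27 ± 0.04. Of the 31 interferon-stimulated genes 5 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00191, adjusted p = 0.420 with an estimated correlation), with STAT1, the transcription factor of the interferon response, at 174 ± 4.72 against 146 ± 5.46 CPM and ISG15 at 18.3 ± 1.96 against 12.3 ± 0.216 CPM (SD, n = 3). Of 30 p53 target genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.00197, adjusted p = 0.314 with an estimated correlation), among them CDKN1A, the cell cycle inhibitor p21, by 0.27 ± 0.05 (log2, SE). Of the 28 lists, camera called 12 at the preset correlation, 0 of them with an estimated one, and fry called 7.

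By fold, the largest rises with ASO3 among genes past the rule were IFITM10, NOXO1, a subunit organizer of an NADPH oxidase, NGFR, the low-affinity neurotrophin receptor, CEND1, IP6K3, GPNMB, IFI6, SCN4B, a sodium channel subunit, SNORD116-4 and CES1, with log2 fold changes from 0.60 (CES1) to 0.85 (IFITM10). SNORD116-4 belongs to a cluster of near-identical small nucleolar RNAs, so its value is uncertain. The largest falls were FAM198A, KIAA0226L, SIM1, FAM196A, LHX9, NMU, a neuropeptide, NTS, neurotensin, KIAA1210, FXYD7 and FBN3, a fibrillin, from -1.69 (FAM198A) to -0.96 (FBN3). NGFR stood at 12.4 ± 1.62 against 7.03 ± 0.524 CPM and FBN3 at 8.25 ± 0.672 against 16.1 ± 1.52 CPM (SD, n = 3; edgeR adjusted p = 0.00280 and 6.36e-05). None of the 20 genes named by fold was among the 17 called for ASO3 against ASO control. Some moved about as far with ASO control, such as IFI6 (log2 1.15). In the authors' deposited tables NTS and GPNMB were at -1.32 and 0.71 with ASO control and at -1.12 and 0.72 with ASO3. Others did not, such as IFITM10 (0.02 and 0.85) and KIAA0226L (-0.09 and -1.25). Of these 20 genes, 6 kept their call without any 1 library: NGFR, SNORD116-4, FAM198A, NMU, FXYD7 and FBN3. Of all 92 called genes followed for this comparison, list members of lowest p included, 45 did. The count of called genes was 512 without ASO3 3, 539 without non-treated 4 and 742 without ASO3 2.

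The control oligonucleotide also changed genes: 44 were called against non-treated cells, 30 higher and 14 lower, and 1726 had an unadjusted p below 0.05. The named rises were IFI6, an interferon-induced mitochondrial protein, ISG15, NDNF, ADHFE1, KCNK3, a background potassium channel, FST, the activin antagonist follistatin, SLC5A1, a sodium-glucose transporter, FGF1, MAP6 and MCUR1, from 0.31 (MCUR1) to 1.15 (IFI6) on the log2 scale. The named falls were TCF21, an epicardial and fibroblast transcription factor, BNIP3, LTBP3, COL9A3, TMED7, PPAP2B, PFKL, a glycolytic phosphofructokinase, KRT19, IGFBP5 and H3F3B, from -0.63 (TCF21) to -0.27 (H3F3B). LTBP3, which tethers latent TGF-beta to the matrix, lies on chromosome 11 (GRCh38, 65538805 to 65558930) and fell from 213 ± 7.59 to 157 ± 8.44 CPM (SD, n = 3; log2 -0.44 ± 0.05 SE, edgeR adjusted p = 1.15e-06). Of the 31 interferon-stimulated genes 3 rose, IFI6, ISG15 and OAS1 (10 adjusted over the list alone; camera adjusted p = 5.64e-06, adjusted p = 0.437 with an estimated correlation), and IFI6 varied widely between libraries at 38.5 ± 18.2 against 17.7 ± 0.804 CPM (SD, n = 3). Its log2 fold change was 0.72 without ASO control 1 and 1.42 without ASO control 4. Of the 25 cholesterol synthesis genes 2 rose, HMGCS1 and SC5D (12 adjusted over the list alone; camera adjusted p = 4.02e-12, adjusted p = 0.117 with an estimated correlation, fry adjusted p = 0.0115). Of the 32 glycolysis and hypoxia genes 2 fell, PFKL and BNIP3 (14 adjusted over the list alone; camera adjusted p = 1.49e-05, adjusted p = 0.344 with an estimated correlation). Of the 28 lists, camera called 13 at the preset correlation, 0 of them with an estimated one, and fry called 1. Of the 20 genes named by fold, 2 kept their call without any 1 library, IFI6 and LTBP3. HMGCS1 and SC5D lost theirs without non-treated 1, non-treated 4 or ASO control 4 (edgeR adjusted p up to 0.158 and 0.218). OAS1 lost its call without any 1 non-treated library, ASO control 1 or ASO control 2 (edgeR adjusted p up to 0.211). The count of called genes was 3 without non-treated 4, 9 without non-treated 1, 10 without ASO control 4, 21 without ASO control 2, 73 without non-treated 3 and 133 without ASO control 1.

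Against ASO control, few genes beyond CALM1 were called in the main fit. With 1 control oligonucleotide, which changed genes itself, this comparison cannot tell exposure to an oligonucleotide as such from effects of that control. For ASO3 the count was 75 with DESeq2, 108 with only the compared groups fitted and 4 with the replicate number as a block. LTBP3 was higher with each of ASO1, ASO3 and ASO4, by 0.37, 0.35 and 0.43 on the log2 scale (SE 0.05 each, edgeR adjusted p = 3.22e-05, 8.44e-05 and 1.16e-06), and it was the control group that differed from non-treated cells. TRNT was likewise lower with ASO control than in non-treated cells (log2 -0.56, edgeR adjusted p = 0.00604, chosen after its values were seen). ASO1 had 2 called genes, CALM1 and LTBP3, with 1007 at an unadjusted p below 0.05. ASO4 had 4: CALM1 and CLK1, a splicing kinase, were lower, and LTBP3 and TRNT (chosen after its values were seen) were higher. For CLK1 the difference came with a rise in the control group: it was at 111 ± 3.23 CPM in non-treated cells, 110 ± 6.18 with ASO4 and 132 ± 5.09 with ASO control (SD, n = 3). Its log2 difference from ASO control was -0.26 ± 0.05 (SE, edgeR adjusted p = 0.0148), a call lost without ASO4 1, ASO4 2 or ASO control 2 (edgeR adjusted p up to 0.413). ASO3 had 17, with 4 higher and 13 lower. RABL6, a RAB-like GTPase on chromosome 9 (GRCh38, 136807943 to 136841187), fell most firmly with ASO3, from 132 ± 2.80 to 90.0 ± 2.92 CPM (SD, n = 3; log2 -0.55 ± 0.05 SE, edgeR adjusted p = 3.63e-09), and it overlaps CCDC183-AS1 and MIR4292. CDH1, the epithelial cadherin, SULT1E1, an oestrogen sulfotransferase, and KCNQ1OT1, an antisense RNA at KCNQ1, also fell, by 0.51, 0.44 and 0.42 on the log2 scale, and CLU and PRKAB2, a subunit of the AMP-activated kinase, rose by 0.27 and 0.22. EMC10, of the membrane protein insertion complex, was at 378 ± 5.33 CPM with ASO3, 525 ± 29.3 with ASO control and 466 ± 62.9 in non-treated cells (SD, n = 3), with an edgeR adjusted p of 0.00108 against ASO control and 0.00807 against non-treated cells. In the authors' deposited table for ASO3 against non-treated cells EMC10 had log2 fold change -0.30 and adjusted p 0.0652. KCNQ1OT1 was not called against non-treated cells (edgeR adjusted p = 0.183). LTBP3, RABL6 and EMC10 kept their calls against ASO control without any 1 library, and CDH1, SULT1E1, KCNQ1OT1, CLU and PRKAB2 did not. The count for ASO3 was 5 without ASO3 3 or ASO control 1, 9 without ASO3 2, 11 without ASO3 4 and 61 without ASO control 4, that for ASO1 41 without ASO control 1, and that for ASO4 2 without ASO4 2 and 7 without ASO4 4.

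**Figure D2:**
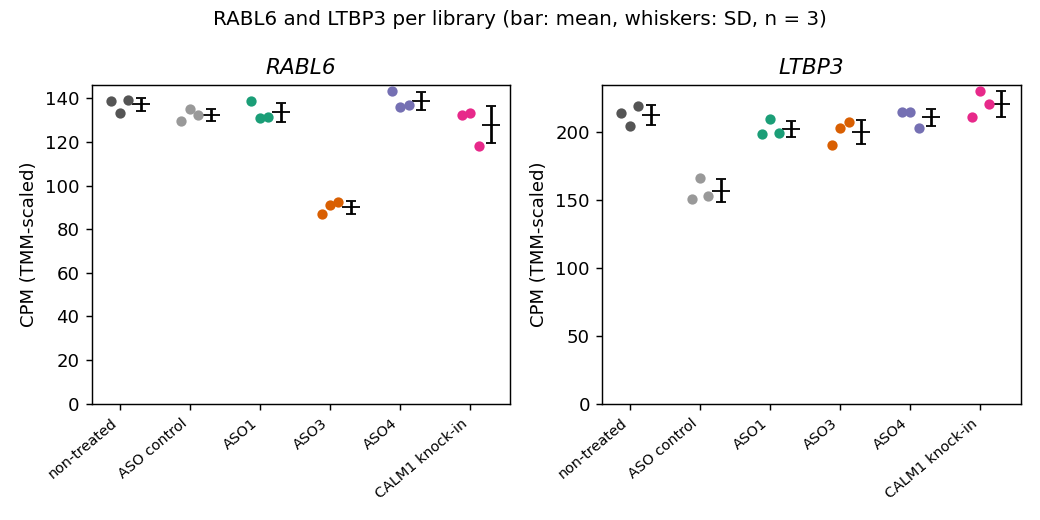
CPM of RABL6 and LTBP3 (vertical axes) in each of the 18 libraries by group, with the mean as a bar and the SD as whiskers (n = 3). RABL6 is at 90.0 CPM with ASO3 and at 128 to 139 CPM in the means of the other 5 groups, and LTBP3 is at 157 CPM with ASO control and at 200.4 to 221 CPM in the others.

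Against ASO control, camera called 3, 12 and 7 of the 28 lists for ASO1, ASO3 and ASO4 at the preset correlation, and 0 with an estimated one. The interferon-stimulated list, itself higher with ASO control than in non-treated cells at the preset correlation, was lower with ASO1 than with ASO control (0 called over all genes, 11 lower adjusted over the list alone; camera adjusted p = 1.98e-08, adjusted p = 0.765 with an estimated correlation). With ASO3 the glycolysis and hypoxia list was higher than with ASO control (0 called over all genes, 15 higher adjusted over the list alone; camera adjusted p = 9.48e-08, adjusted p = 0.204 with an estimated correlation). That list was itself lower with ASO control than in non-treated cells at the preset correlation. With ASO4 the respiratory chain list was lower (0 called over all genes and 0 adjusted over the list alone; camera adjusted p = 5.15e-05, adjusted p = 0.751 with an estimated correlation). Of the 1184 genes called for ASO3 against non-treated cells, 15 were also called in the same direction against ASO control. The same sign was seen there for 1150 (97.1%). The median size was 0.25 on the log2 scale against non-treated cells, and along that direction 0.12 for ASO3 against ASO control and 0.14 for ASO control against non-treated cells. These genes were selected with the same ASO3 and non-treated libraries, which favours a shared sign. The share of equal signs without change was not computed.

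Among the 3 targeting oligonucleotides, 598 genes differed in the joint edgeR test. The pairwise contrasts called 750 genes for ASO3 against ASO1, 107 for ASO4 against ASO3 and 1 for ASO4 against ASO1, TRNT (chosen after its values were seen). The 10 genes of lowest p were RABL6, TGFBR1, the type 1 receptor of TGF-beta, RDH10, a retinol dehydrogenase, CDH1, GPR126, MYRF, PRKAB2, ANXA8L1, COLEC12 and SFRP5, a secreted Wnt antagonist. All had their lowest mean with ASO3 except PRKAB2, which had its highest. RABL6 was at 134 ± 4.34, 90.0 ± 2.92 and 139 ± 3.94 CPM with ASO1, ASO3 and ASO4 (edgeR adjusted p = 8.46e-11), and TGFBR1 at 91.2 ± 1.06, 68.5 ± 4.65 and 81.6 ± 5.17 CPM (SD, n = 3; edgeR adjusted p = 2.54e-04). The joint count was 130 without ASO3 3, 196 without ASO1 1, 278 without ASO1 3, 282 without ASO3 2, 373 without ASO3 4 and 383 without ASO1 4.

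The CALM1 knock-in cells differed from non-treated wild-type cells far more than any treated group. The edgeR test called 7199 of 16968 genes, 3534 higher and 3665 lower, of which 1239 changed at least 2-fold. Most genes of the contractile apparatus were higher, and most markers of fibroblasts and epicardium were lower. Many genes of oxidative metabolism were higher and most cell cycle genes lower, though these lists lost their call with an estimated correlation. Of the 30 sarcomere genes 28 rose and 0 fell (28 adjusted over the list alone; camera adjusted p = 4.67e-17, adjusted p = 0.0406 with an estimated correlation). ANKRD1 rose from 1984 ± 129 to 4431 ± 315 CPM (SD, n = 3; log2 1.16 ± 0.06 SE, edgeR adjusted p = 3.94e-16), and MYL3, a ventricular light chain, MYH6, the alpha myosin heavy chain, and MYOZ2 rose by 0.86, 0.89 and 0.69 on the log2 scale. Of 18 fetal and stress-response genes 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 9.05e-05, adjusted p = 0.0747 with an estimated correlation), with NPPA, the atrial natriuretic peptide, at 3669 ± 99.3 against 1391 ± 60.05 CPM (SD, n = 3). Of 26 calmodulin effectors and feedback regulators 15 rose and 4 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.00191, adjusted p = 0.0406 with an estimated correlation), led by RCAN2, a calcineurin regulator, MYLK, a myosin light chain kinase, and CAMK2B with log2 fold changes of 0.84, 0.74 and 0.85. Of 27 calcium handling genes 16 rose and 5 fell (16 and 5 adjusted over the list alone; camera adjusted p = 0.00283, adjusted p = 0.120 with an estimated correlation), among them HRC by 0.88 and TRDN, triadin, by 0.80, while ITPR2, an inositol trisphosphate receptor, fell by 0.89. JPH2, junctophilin, rose by 0.95 and lies on the long arm of chromosome 20.

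Of 37 nuclear-encoded respiratory chain genes 36 rose in knock-in cells (36 adjusted over the list alone; camera adjusted p = 2.37e-16, adjusted p = 0.0720 with an estimated correlation), led by SDHA, NDUFS2 and NDUFS1 at 0.63, 0.55 and 0.50 on the log2 scale. Of 28 fatty acid oxidation genes 17 rose and 0 fell (17 adjusted over the list alone; camera adjusted p = 2.73e-06, adjusted p = 0.0568 with an estimated correlation), with FABP3, the heart fatty acid-binding protein, at 715 ± 14.2 against 387 ± 20.8 CPM (SD, n = 3). Of 35 cell cycle genes 32 fell and 1 rose (32 and 1 adjusted over the list alone; camera adjusted p = 9.83e-14, adjusted p = 0.0720 with an estimated correlation). MKI67, a proliferation marker, fell from 111 ± 7.54 to 50.9 ± 7.31 CPM (SD, n = 3), CENPF fell by 0.98 on the log2 scale, and PCNA, on the short arm of chromosome 20, fell by 0.80. Of 33 unfolded protein response and ATF4 target genes 22 fell and 1 rose (23 and 1 adjusted over the list alone; camera adjusted p = 4.32e-07, adjusted p = 0.0406 with an estimated correlation), among them the serine synthesis enzymes PHGDH and PSAT1 by 0.96 and 1.27 on the log2 scale. Of 39 ribosomal protein genes 26 fell (27 adjusted over the list alone; camera adjusted p = 1.65e-05, adjusted p = 0.371 with an estimated correlation), with RPS3 at 528 ± 22.6 against 643 ± 9.54 CPM (SD, n = 3). Of 28 lysosome and autophagy genes 17 rose and 3 fell (17 and 3 adjusted over the list alone; camera adjusted p = 2.67e-04, adjusted p = 0.139 with an estimated correlation), led by CTSB, cathepsin B, which rose by 0.99 ± 0.04 (log2, SE).

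Markers of other cell types moved with the knock-in group in both directions. Of 25 fibroblast and matrix genes 21 fell and 2 rose (22 and 2 adjusted over the list alone; camera adjusted p = 1.49e-10, adjusted p = 0.0406 with an estimated correlation): DCN, decorin, fell from 357 ± 34.4 to 60.0 ± 4.35 CPM and POSTN, periostin, from 176 ± 8.29 to 43.5 ± 1.303 CPM (SD, n = 3). Of 18 smooth muscle and epicardial markers 14 fell and 3 rose (14 and 3 adjusted over the list alone; camera adjusted p = 1.39e-05, adjusted p = 0.0406 with an estimated correlation), with ITLN1, ALDH1A2, BNC1 and KRT19 at log2 fold changes of -3.72, -3.54, -2.59 and -1.83. Of 16 endoderm and liver genes 12 rose (13 adjusted over the list alone; camera adjusted p = 1.65e-05, adjusted p = 0.0802 with an estimated correlation), and the median of the list was 2.45 on the log2 scale. AFP, alpha-fetoprotein, was at 67.9, 147 and 57.3 CPM in CALM1 knock-in 1, 3 and 4, against 4.65 ± 1.51 CPM in non-treated cells (SD, n = 3), and SERPINA1 at 36.3, 86.3 and 41.9 CPM against 2.27 ± 0.795 CPM. Endothelial markers (4 rose and 4 fell of 14), pluripotency markers (4 and 5 of 11), neural markers (2 and 6 of 12) and skeletal muscle markers (1 and 1 of 7) were not called as lists, with camera adjusted p-values of 0.672, 0.568, 0.293 and 0.293.

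By fold, the largest rises in knock-in cells were mostly liver and endoderm genes: SERPINA1, ALB, serum albumin, AHSG, AFP, TM4SF4, AMBP, APOA2, HABP2, TDGF1, a Nodal co-receptor, and HSPB6, a small heat shock protein, with log2 fold changes from 2.79 (HSPB6) to 4.57 (SERPINA1). ZNF502 and ZIC1, a zinc finger transcription factor of neural and mesodermal tissue, had 0 reads in the 3 knock-in libraries. Against a floor of 3 counts over the group they were at least 38.1-fold and 36.4-fold lower than the 2.13 ± 0.154 and 2.04 ± 0.210 CPM of non-treated cells (SD, n = 3). ELN, elastin, and CPB1 had 2 and 5 reads over the knock-in group against 178 and 439 over the non-treated group. Further falls were CES1, LINC01139, CYP26A1, a retinoic acid hydroxylase, TNFSF18, NEFM, a neurofilament, and ITLN1, from -5.32 (CES1) to -3.72 (ITLN1) on the log2 scale. All 20 of these genes kept their call without any 1 library. CALM1 was lower at 166 ± 6.44 CPM (SD, n = 3; log2 -0.14 ± 0.05 SE, edgeR adjusted p = 0.0134), a call lost without non-treated 3 (-0.13, edgeR adjusted p = 0.0510) or CALM1 knock-in 1 (-0.12, edgeR adjusted p = 0.0547). CALM2 and CALM3 changed by -18.03% and -18.99% (edgeR adjusted p = 3.24e-06 and 3.05e-07). Of the 28 lists, camera called 17 at the preset correlation and 5 with an estimated one (sarcomere, calmodulin effectors, unfolded protein response, fibroblast, and smooth muscle and epicardium), and fry called 26.

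**Figure D3:**
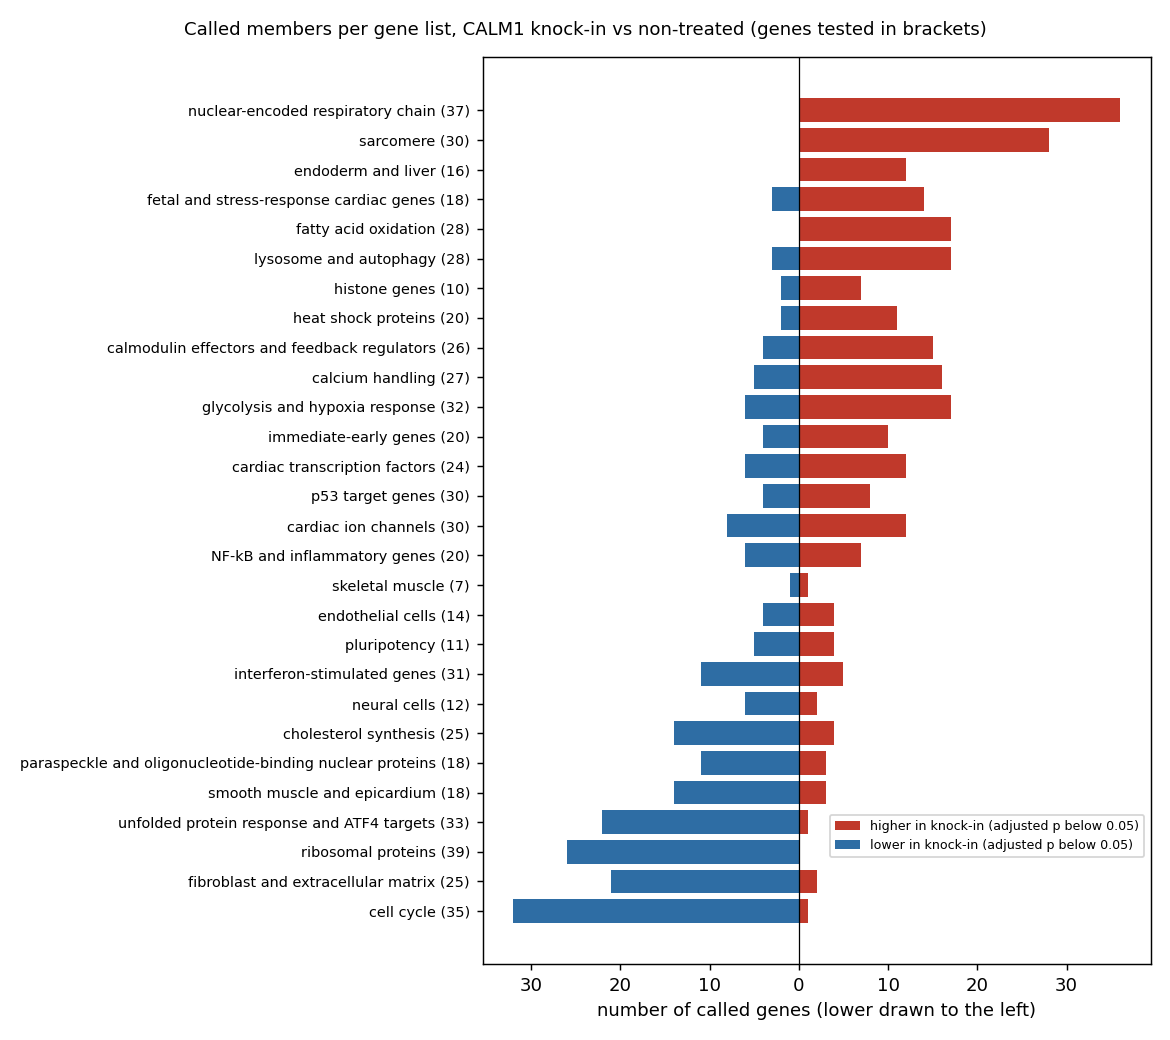
Number of genes per list called higher (right) or lower (left) in CALM1 knock-in against non-treated cells (horizontal axis), with the number tested in brackets. The respiratory chain (36 of 37) and sarcomere (28 of 30) lists were almost all higher, and the cell cycle list (32 of 35) almost all lower.

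Genes on chromosome 20 stood apart in the knock-in libraries. Short-arm genes had a median log2 fold change of -0.89 and long-arm genes 0.43 against non-treated cells, and the sign changed at the gap between 26208186 and 30377164 (GRCh38). Per library the medians were -0.84, -0.91 and -0.83 for the short arm and 0.40, 0.42 and 0.41 for the long arm. On the other autosomes, runs of 116 neighbouring genes, as many as on the short arm, had medians from -0.14 to 0.16, and runs of 253, as many as on the long arm, from -0.08 to 0.08. Both arms lay within 0.02 of 0 in the 4 oligonucleotide groups. The edgeR test called 323 of the 412 tested chromosome 20 genes (78.4%) and 43.2% of genes placed elsewhere. Without chromosome 20, 6716 of 15498 placed genes were called, 3262 higher and 3454 lower.

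**Figure D4:**
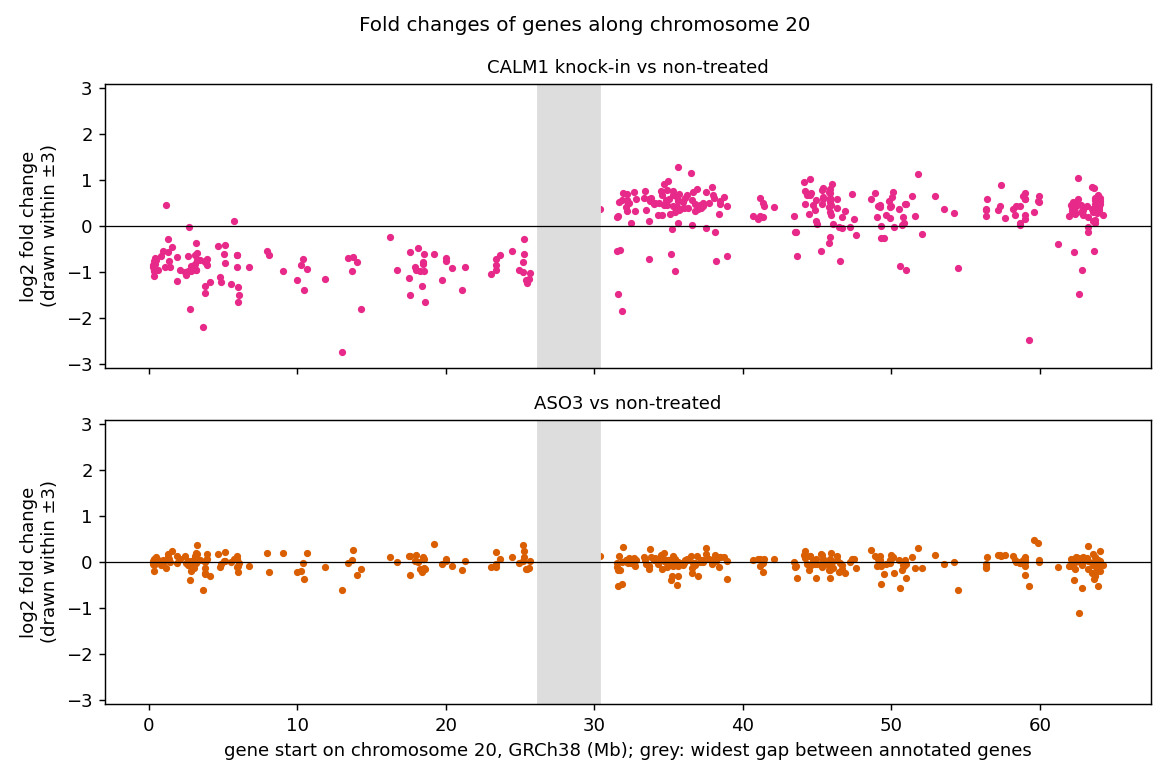
Log2 fold change (vertical axes) of genes along chromosome 20 (horizontal axis, Mb, GRCh38) in CALM1 knock-in and in ASO3 libraries against non-treated cells, with the gap between the arms in grey. In knock-in cells most short-arm genes lie below 0 (median -0.89) and most long-arm genes above 0 (median 0.43), and with ASO3 both arms centre on 0.

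The oligonucleotide effects, taken against ASO control, were compared with the knock-in effect across 16968 genes, which are not independent replicates. Pearson's r was -0.0993 for ASO1, 0.210 for ASO3 and 0.0298 for ASO4. The value for ASO1 was -0.0401 without ASO1 1, -0.0382 without ASO control 2, -0.0597 without ASO control 4 and -0.287 over genes with a mean of at least 10 CPM. The value for ASO3 was 0.129 without ASO control 1 and 0.490 over genes with a mean of at least 10 CPM. That for ASO4 turned negative without ASO control 1 (-0.0340), ASO4 1 (-0.0122) or ASO4 2 (-0.00273) and over genes with a mean of at least 10 CPM (-0.0107). It was 0.00525 without non-treated 1, 0.0137 without CALM1 knock-in 1, 0.0537 without ASO control 2 and 0.0610 without ASO4 4. Of the genes called for ASO3 against ASO control, 2 of 4 higher and 9 of 13 lower genes were called in the same direction in knock-in cells, where independent lists would share 0.833 and 2.81. The lower genes include CALM1, the target, also called lower in knock-in cells, and PROCR, on the long arm of chromosome 20. The numbers for independent lists take no account of expression level.

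Calls against the shared non-treated libraries overlapped between ASO3 and ASO control, with 30 genes higher in both and 8 lower in both. Independent lists would share 1.01 and 0.504. Simulated groups without change shared 0, but groups without change have few calls to share, so this sets no reference for the shared calls. Fold changes of the pair had a covariance of 0.0110 against 0.00402 simulated, and r was 0.665 against 0.489. The simulated comparisons share their non-treated libraries too, so the simulated covariance includes noise from sharing. The 3 non-treated libraries were not split between the comparisons, so part of the excess may come from them. ASO control 4 may add to it. On the fourth principal component it was at -15.3, beside the ASO3 libraries at -12.6, -15.3 and -11.2. ASO control 1 and 2 were at 4.85 and -3.72. Without it the calls fell from 44 to 10 for ASO control against non-treated cells and rose from 17 to 61 for ASO3 against ASO control. The covariance was 0.00941 against 0.00405 for ASO3 and ASO4, 0.00828 against 0.00403 for ASO4 and ASO control, 0.00543 against 0.00407 for ASO1 and ASO control, 0.00500 against 0.00410 for ASO1 and ASO3, and 0.00340 against 0.00409 for ASO1 and ASO4.

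The authors' deposited tables list adjusted p-values under 0.05 for 32 genes with ASO1, 1506 with ASO3, 69 with ASO4 and 105 with ASO control. In that order they give an adjusted p for 7380, 13975, 2755 and 11432 genes, against 16968 in the refit. The refit also called 1 of the 32, 1133 of the 1506, 1 of the 69 and 35 of the 105. The fold changes in the authors' deposited tables correlated with the refitted ones across genes at 1.000 for ASO1, ASO3 and ASO4 and at 0.846 for ASO control. CALM1 had log2 fold change -0.38 and adjusted p 9.88e-16 with ASO1 in the authors' deposited table.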

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

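All tests of explanations and splits of the samples in this part were chosen after the results were seen.

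RABL6 with ASO3 and LTBP3 with ASO control were each lower with 1 oligonucleotide only among those tested, by 0.57 (log2 -0.57 for ASO3 minus ASO1) for RABL6. Reads counted for overlapping genes were fewer than those lost. CCDC183-AS1 and MIR4292 together held 8.67 CPM in non-treated cells, where RABL6 was at 137 CPM, against 90.0 CPM with ASO3. LTBP3 had 0 CPM in overlapping genes of the table. Ambiguous reads, and antisense reads counted for RABL6 or LTBP3, were not examined, so shared reads are not ruled out. No 1 library carried either change, with edgeR adjusted p at most 3.90e-08 for RABL6 and 5.77e-05 for LTBP3 without any 1 library. Neighbouring genes had median log2 changes of -0.0645 and -0.00719, which argues against a change of the whole region. A sequence-dependent action of the oligonucleotide on these transcripts may remain as an untested hypothesis, since oligonucleotide sequences were not used here.

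The joint edgeR test among ASO1, ASO3 and ASO4 called 598 genes, and CALM1 differed by -0.32 on the log2 scale between ASO4 and ASO3. In 100 splits drawn from the 280 possible ones of the 9 libraries, 1, the real one, called as many genes, and the highest other called 416, a share under 0.05. In the library CALM1 knock-in 3, 12.5% of reads aligned to several places, above the highest non-treated library at 5.51%. In CALM1 knock-in 4, 19.0% of reads fell in no annotated feature, above the highest non-treated library at 16.9%. CALM1 knock-in 1 was at 18.8%, and CALM1 knock-in 3, at 16.1%, lay below every non-treated library. This share was also above every non-treated library (16.2 to 16.9%) in all libraries of ASO3 (17.1 to 17.4%), ASO4 (17.1 to 17.3%) and ASO control (17.4 to 17.8%).

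For pairs of groups, 3 against 3 makes 10 splits, too few for a share under 0.05. Against non-treated cells the real counts and the highest of the other splits were 2 and 3 for ASO1, 1184 and 1 for ASO3, 1 and 1 for ASO4, 44 and 5 for ASO control, and 7199 and 0 for the knock-in. Against ASO control they were 2 and 1 for ASO1, 17 and 1 for ASO3, and 4 and 13 for ASO4. The split with 13 put ASO4 1 and ASO4 2 with ASO control 4, which points to a structure of these samples other than their groups.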

How the results depend on the processing

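The tests without the knock-in libraries and without chromosome 20 were chosen after the results were seen. CALM1 kept its direction and its call against non-treated cells and ASO control with ASO1, ASO3 and ASO4 under every alternative. Of 268 named gene results, 187 kept direction and side of the threshold in every setting that gave an adjusted p. In some setting 78 lost the call. The knock-in comparison carries much of this stability. Leaving out any 1 library, 122 of its 122 followed calls other than calmodulin genes were kept. For ASO3 and ASO control against non-treated cells, 45 of 92 and 2 of 27 were kept. A call of this kind depends on 3 libraries per group and on the depth reached, and where a fit leaves out a library the other groups set the spread. The cause of the differences below was not tested.

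Without a filter on low counts the number of called genes was 61 for ASO1, 148 for ASO4 and 281 for ASO control against non-treated cells, 77, 227 and 39 for ASO1, ASO3 and ASO4 against ASO control, and 994 in the joint test. With DESeq2 it was 14 for ASO1, 97 for ASO4 and 160 for ASO control against non-treated cells, and 75 for ASO3 and 13 for ASO4 against ASO control. In the simulated data set for ASO3 DESeq2 made 21 false calls (10.1%) and edgeR 7 (3.66%). Fitting only the compared groups gave 31, 1808, 13 and 139 for ASO1, ASO3, ASO4 and ASO control against non-treated cells, 16 and 108 for ASO1 and ASO3 against ASO control, and 987 in the joint test. Without the knock-in libraries the counts were 6 for ASO1, 14 for ASO4 and 118 for ASO control against non-treated cells, 7 and 90 for ASO1 and ASO3 against ASO control, and 915 in the joint test. All of these were above the main fit, although fewer libraries were fitted. Knock-in replicates differed by a chi-square per degree of freedom of 4.80 to 9.23, those of other groups by 2.63 to 6.70. Whether this spread lowers the oligonucleotide counts of the main fit was not tested. The knock-in count stayed within 1.5 times of 7199 under every alternative, and DESeq2 size factors moved no count that far.

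Replicate numbers do not pair the samples: across 34 pairs of equal number r ran from -0.0662 to 0.0778, and 5 of 18 libraries matched their own number best. With the number as a block the counts were 748 for ASO3 and 26 for ASO control against non-treated cells, 4 for ASO3 against ASO control and 240 in the joint test, and 5 lists were called for ASO1 against ASO control in place of 3.

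Leaving out 1 library at a time, the counts ran from 1 to 10 for ASO1, 512 to 988 for ASO3, 1 to 131 for ASO4, 3 to 133 for ASO control and 6381 to 6992 for the knock-in against non-treated cells. Against ASO control they ran from 2 to 41 for ASO1, 5 to 61 for ASO3 and 2 to 7 for ASO4, and in the joint test from 130 to 829. CALM1 in the knock-in comparison ran from -0.17 to -0.12 on the log2 scale. The similarity to the knock-in ran from -0.123 to -0.0382 for ASO1, 0.129 to 0.207 for ASO3 and -0.0340 to 0.0610 for ASO4, and over genes with a mean of at least 10 CPM it was -0.287, 0.490 and -0.0107.

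CALM2, called in none of the comparisons named here, changed sign near 0. For ASO control against non-treated cells it was -0.00471 without a filter, -0.00120 with the compared groups alone, -8.45e-04 without the knock-in libraries, -0.0246 without non-treated 4 and -0.0220 without ASO control 1, and at most 0.0176 (without non-treated 1). For ASO3 against non-treated cells it was 0.00142 with the block, 0.0149 without non-treated 1, 0.00370 without non-treated 3 and 0.0211 without ASO3 3, and at lowest -0.0275 (without non-treated 4). For ASO3 against ASO control it was 0.0214 without ASO3 3 and 0.0188 without ASO control 1, and at lowest -0.0207 (without ASO3 2).

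With an estimated correlation camera called 0 lists in every oligonucleotide comparison and 5 for the knock-in. In the order ASO1, ASO3, ASO4, ASO control and knock-in against non-treated cells fry called 1, 7, 0, 1 and 26 lists, and 0 in each comparison with ASO control. With DESeq2, calls shared against non-treated cells numbered 10 for ASO1 and ASO3, 2 for ASO1 and ASO4, 9 for ASO1 and ASO control, 72 for ASO3 and ASO4, 127 for ASO3 and ASO control, and 25 for ASO4 and ASO control. With edgeR they numbered 1, 1, 1, 1, 38 and 0.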

Other observations

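The tests of the chromosome 20 pattern and of the knock-in change, and the contrasts of each arm with all others, were chosen after the results were seen.

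Members of further gene groups changed in knock-in cells, though none of these lists was called with an estimated correlation. Of 20 heat shock proteins 11 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00288, adjusted p = 0.316 with an estimated correlation), with HSPB8 and CRYAB, small heat shock proteins of muscle, higher by 0.69 and 0.76 on the log2 scale and HSPA1A lower, at -1.35. Of 25 cholesterol synthesis genes 14 fell and 4 rose (14 and 4 adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.371 with an estimated correlation), among them SQLE and HMGCR, rate-limiting enzymes, at -0.61 and -0.40. Of 32 glycolysis and hypoxia genes 17 rose and 6 fell (17 and 6 adjusted over the list alone; camera adjusted p = 0.0110, adjusted p = 0.387 with an estimated correlation), with ENO2 at 1.48 and SLC2A3, a glucose transporter, at 0.77. Of 18 paraspeckle and oligonucleotide-binding proteins 11 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.00510, adjusted p = 0.141 with an estimated correlation), with HNRNPA1 at -0.54, NEAT1 at 0.92 and XRN2, on the short arm of chromosome 20, at -0.89. Among ion channels, GJA5, connexin 40, fell by 1.46 on the log2 scale, and HCN4 and KCNQ1 rose by 0.45 and 0.66, with 12 of 30 higher and 8 lower (13 and 9 adjusted over the list alone; camera adjusted p = 0.293). CKM, muscle creatine kinase, rose from 127 ± 3.35 to 349 ± 6.84 CPM (SD, n = 3).

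When each arm was set against the mean of the other oligonucleotide arms and non-treated cells, edgeR called 20 genes for ASO1, 1286 for ASO3, 2 for ASO4 and 4 for ASO control. Other arms produce some of these calls: RABL6 at 0.19 for ASO4 reflects its low level with ASO3, and CALM1 at 0.38 for ASO control its low level with ASO1, ASO3 and ASO4. Ordered by edgeR adjusted p, RABL6 led for ASO3 at -0.59, followed by LOC100996760 at -0.39 and PRKAB2 at 0.28 on the log2 scale. Changes of LOC101927940 (0.77) and SBSPON (-0.63) were larger.

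In all 3 knock-in libraries chromosome 20 genes split by arm. The highest short-arm median of a knock-in library was -0.83, so the pattern does not rest on 1 library. The largest median was 0.0721 in size among 38 pieces of the other autosomes and 0.159 among all runs of 116 neighbouring genes there, which argues against cell state or composition as the whole cause. All 13 bins of 5 Mb moved with their arm, with medians from -1.01 to -0.84 on the short arm and from 0.29 to 0.50 on the long arm, and 10000 random gene lists of the same size and level gave medians from -0.107 to 0.113 for the short arm and from -0.0755 to 0.0935 for the long arm. A candidate explanation is altered dosage of both whole arms, such as loss of short-arm and gain of long-arm copies in the knock-in line, which these RNA data cannot show directly.

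The genome-wide knock-in change does not rest on 1 library, since at least 6437 genes were still called without any 1 knock-in library, nor on chromosome 20, since 6716 calls lay elsewhere. A higher share of cardiomyocytes alone would lower the markers of every other cell type, while the endoderm and liver list had a median of 2.45 on the log2 scale and the smooth muscle and epicardial list -1.15. Genotype, clone and differentiation stay open and untested, since the labels name no second or corrected knock-in line, and a chromosome 20 change may act on genes elsewhere.

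The authors' deposited table for ASO control correlated at 0.838 with the ratio of mean CPM from the 3 control libraries across 11781 genes with a mean of at least 5 CPM, a different calculation from the model fold changes of the report. On that measure it correlated at 0.899 with ASO control 1 and 2 alone, and at 0.520 with ASO control 4 alone. No other subset of the control libraries correlated higher than 0.899. The measure was not computed for the other deposited tables, so which libraries entered the ASO control table stays open.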
